A study of Mus musculus with 12 samples.

How the data were processed

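Total RNA of gonadal white fat from male mice of 4 genotypes was pooled from 3 animals per array, labelled with Cy3 and hybridized to 12 one-colour arrays, 3 per genotype. The deposited scanner files hold, per the file headers, intensity values from Feature Extraction 10.7.3.1, among them a processed signal that the software had subtracted for background and detrended within the array, with no scaling between arrays, and the raw median signal of each spot and of its local background. The deposited table of processed values is in log2 units; the authors name limma 3.26.9, and the columns share nearly the same quartiles, as after quantile normalization. That table keeps 38927 probes by a filter that is not stated. Each of its columns correlated with the scanner values of its own array at 0.815 or higher, as deviations from the mean over arrays, and with another array at 0.414 at most.

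The scanner files were used. Spots marked by the software were left out, and the log2 processed signal of the other spots of a probe was averaged. It was then shifted so that each array had the same 75th percentile. In all, 94 probes were dropped because marked spots left them without a value on an array. Of 55681 distinct probes, 29150 carry a RefSeq accession and 27503 were named through it, for 20883 genes; 1647 accessions were not matched, and 26531 probes without one stay unnamed. A table of the GRCm38.p6 assembly was used for names and for which genes neighbour each other, and the array's own grid was made on an older assembly. Probes well above background on at least 3 of 12 arrays were kept, with 1 probe per gene, the one with the highest mean, which left 31455 genes or unnamed probes. A gene below background in a whole group has its fold given as a lower bound, against the lowest signal that the software called above background.

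Linear models were fitted with limma 3.58.1 in R 4.3.3 to all 12 arrays with 4 genotype means, which leaves 8 residual degrees of freedom, with an intensity trend and robust empirical Bayes moderation. Tests are two-sided, and p values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The comparisons are each knockout against WT, DKO against each single knockout, and the interaction, the effect of Ing1 loss without Gadd45a less that with it. An exact test of 3 arrays against 3 cannot go below a p of 0.1. In all, 32 gene lists were tested per comparison with camera at a preset correlation between genes of 0.01, and again with the correlation estimated from the data, with adjustment over the 32 lists. Members were counted over all genes and adjusted over the list alone. With the preset, 16, 16, 20, 22, 17 and 20 lists passed in the 5 comparisons between groups and the interaction, and 0 with an estimated correlation. Between 1 and 4 lists per comparison had a median of another sign than camera's direction, and between 1 and 3 a mean of another sign than the median. Called genes within 20 Mb of Ing1 and Gadd45a were compared with the others by Fisher's exact test. Correlations against shared WT arrays stand beside the mean of 20 simulations of unchanged groups.

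The design, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. Named are Gadd45a and Ing1; in each comparison against WT the 10 largest rises and the 10 largest falls among named genes past the threshold whose values do not overlap between the groups, and in the other comparisons the 5 largest each way; where none pass, the 5 genes with the smallest p; and up to 4 members of each list described, those with the smallest p. Clones and predicted genes were passed over. The alternatives were quantile normalization, centring on the median, normexp background correction with an offset of 50, the authors' values, no filter and a filter on all 12 arrays, every probe tested, plain empirical Bayes, only the arrays compared, the replicate number, array row or array column as a block, each array left out in turn, and the estimated correlation. Normexp used the median spot signal, since the files hold no mean signal. It moved the median log2 fold change of all genes to -0.13 in Ing1-KO against WT, -0.10 in DKO against WT and 0.12 in the interaction, against -0.04, -0.05 and 0.01. Added after the data were seen were a fit without the 3 arrays highest in skeletal muscle transcripts, a fit with slide and array row, a fit without 2 arrays, genes at an unadjusted p under 0.01 near the targeted genes, and the fold changes of Ing1 and Gadd45a with only the arrays compared.

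The replicate number equals the slide and the scan. The fit was tested on simulated data with 200 changed genes among 31455: of those changed 2-fold it recovered 45.2% in Gadd45a-KO against WT, 50% in Ing1-KO against WT, 47.5% in DKO against WT, 49.2% in DKO against Gadd45a-KO and 33.8% in DKO against Ing1-KO, with 2 to 7 false calls. A simulated list moved by 0.5 on the log2 scale was called with both correlations in all 6 comparisons, and 0 other lists were. The simulated genes were drawn independently of each other. So this does not test for false list calls where the genes of a list vary together.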

Results

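Gene expression was measured in gonadal white fat of male C57BL/6N mice of 4 genotypes: wild type (WT), mice lacking Gadd45a (Gadd45a-KO), mice lacking Ing1 (Ing1-KO) and mice lacking both (DKO). Gadd45a encodes a stress-induced protein with known roles in DNA repair and DNA demethylation, and Ing1 encodes a chromatin reader that binds trimethylated lysine 4 of histone H3. Each genotype is represented by 3 one-colour arrays, and each array holds RNA pooled from 3 animals aged 59 to 67 days, so that 9 animals stand behind each genotype. The 12 arrays lie on 3 slides, and each slide carries 1 array of every genotype. The median processed signal per array lay between 39.3 and 68.8 intensity units, the 75th percentile between 455.6 and 894.2, and between 58.2% and 68.1% of the 59305 spots per array were well above background. The lowest value of each of these ranges was that of WT replicate 2. In all, 31455 genes or unnamed probes were tested, of which 15950 carry a gene name, and the number of arrays limits the precision.

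The Ing1 transcript was much lower in the arrays labelled as lacking Ing1, on each of 3 probes. On the brightest probe the mean normalized log2 signal was 12.46 ± 0.03 in WT and 12.55 ± 0.21 in Gadd45a-KO, against 9.40 ± 0.13 in Ing1-KO and 9.32 ± 0.25 in DKO (SD, n = 3 arrays each). This is an 8.35-fold lower signal in Ing1-KO and an 8.80-fold lower signal in DKO than in WT. The dimmest of the 3 probes was above background on 0 of the 6 arrays labelled as lacking Ing1, where its signal was at least 18.3-fold lower in Ing1-KO and at least 15.8-fold lower in DKO. The single Gadd45a probe behaved otherwise. Its mean normalized log2 signal was 9.51 ± 0.25 in WT and 9.20 ± 0.12 in Ing1-KO, against 10.17 ± 0.11 in arrays labelled Gadd45a-KO and 10.61 ± 0.01 in arrays labelled DKO (SD, n = 3 each). All 6 arrays labelled as lacking Gadd45a, between 10.05 and 10.62, lay above all 6 others, between 9.06 and 9.80. The probe thus sets the arrays apart by their Gadd45a label. Where it lies relative to the deleted part of the gene is not known, so it does not tell which set of 6 lacks Gadd45a. Every statement below about Gadd45a holds only if its labels are right, which the data do not decide.

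**Figure D1:**
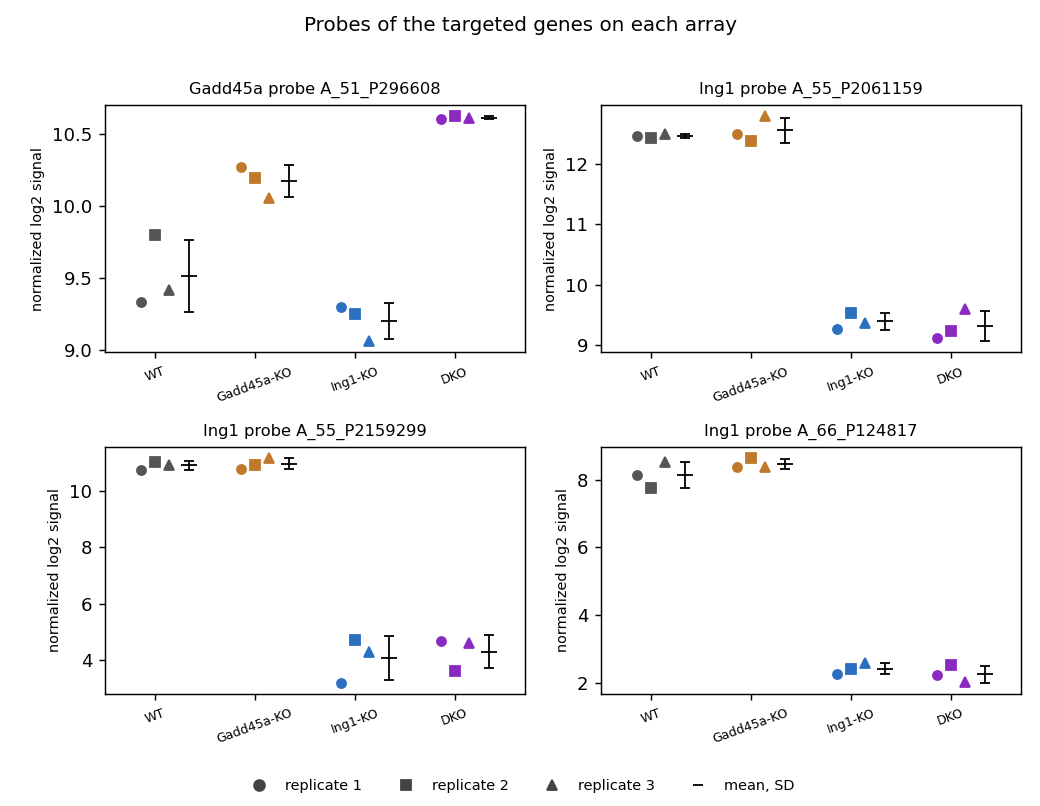
Normalized log2 signal (y axis) of the Gadd45a probe and the 3 Ing1 probes on each array, by genotype (x axis), with symbols for the replicate number and the mean with its SD beside them. The 3 Ing1 probes are low in Ing1-KO and DKO, and the Gadd45a probe is higher in the arrays labelled Gadd45a-KO and DKO, between 10.05 and 10.62, than in the others.

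The first comparison, Gadd45a-KO against WT, asks what loss of Gadd45a alone does to the fat transcriptome. No gene passed. The genes with the smallest p, none of which pass, were Cd207, a receptor of Langerhans-type dendritic cells, with a log2 fold change of 1.74 ± 0.26 (SE, n = 3 arrays per group), and the chemokine Ccl12 with 0.90 ± 0.15. They were followed by the phospholipase Pla2g4a with 0.59 ± 0.11, the prostaglandin transporter Slco2a1 with 0.71 ± 0.13, and the neutrophil granule peptide Camp with 3.22 ± 0.63. Their adjusted p lay between 0.722 and 0.9998. Of these genes, Cd207 lies within 20 Mb of Gadd45a. The Gadd45a probe itself had a log2 fold change of 0.66 ± 0.13 in the arrays labelled Gadd45a-KO, with an adjusted p of 0.9998.

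Neutrophil and mesothelial transcripts stood highest among the gene lists in Gadd45a-KO. Neutrophil and mast cell markers had a median log2 fold change of 1.63 over 15 measured members, of which 0 passed over all genes and 7 rose when adjusted over the list alone. Examples are the granule protein genes Camp, Ngp with 3.43 ± 0.88, which is imprecise since only 2 of 3 WT arrays were above background, and the calprotectin subunits S100a9 with 3.25 ± 0.78 and S100a8 with 2.99 ± 0.81. The list as a whole passed camera with an adjusted p of 1.41e-13, but with adjusted p = 0.183 with an estimated correlation. Mesothelial markers, genes of the lining of the abdominal organs such as Krt19 with 1.35 ± 0.51, had a median of 1.35 over 7 members, with 1 that rose adjusted over the list alone, and adjusted p = 0.183 with an estimated correlation. The mean of the neutrophil and mast cell list, as a deviation from its mean over 12 arrays, was 2.12, 1.45 and 0.54 in the 3 Gadd45a-KO arrays, and that of the mesothelial list was 1.63, 0.83 and 0.17 in the same arrays. Without Gadd45a-KO replicate 1 the mesothelial median was 0.86. The sizes depend on the handling of dim probes: the neutrophil and mast cell and the mesothelial medians were 0.41 and 0.29 with normexp background correction and 1.07 and 0.56 with no filter. With the filter on all 12 arrays the neutrophil and mast cell median was 0.42, and with the authors' values 1.08.

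Fat cell transcripts lay slightly lower in Gadd45a-KO, a lean that rests largely on WT replicate 2. That array was the dimmest of the 12, with a median processed signal of 39.3 units. All 24 white adipocyte markers had a negative log2 fold change, with a median of -0.27, for example the retinol carrier Rbp4 with -0.73 ± 0.23 and the adipokine Retn with -0.55 ± 0.25. All 20 genes of de novo lipogenesis did so too, with a median of -0.39, among them the desaturase Scd1 with -0.40 ± 0.18 and the fatty acid synthase Fasn with -0.66 ± 0.34. All 25 proliferation genes had a positive value, with a median of 0.27. None of these members passed, over all genes or adjusted over the list alone, and the adjusted p of the 3 lists was 0.565, 0.565 and 0.589 with an estimated correlation. Over 31455 genes limma called 0, with 739 genes at an unadjusted p under 0.05 where chance gives 1573, and the 2 groups did not overlap for 8.11% of genes, where chance gives 10%. Leaving out WT replicate 3 gave 1 gene. Without WT replicate 2 the calls of all 3 lists were lost, at medians of -0.05 for white adipocyte markers, -0.17 for lipogenesis and 0.13 for proliferation, and 4 lists passed in place of 16. Without Gadd45a-KO replicate 3 the lipogenesis call was lost too, at -0.15, and 9 lists passed, and without Gadd45a-KO replicate 1 its median was -0.61. The proliferation median was 0.16 with the array column as a block.

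The comparison of Ing1-KO with WT asks what loss of Ing1 alone does. Ing1 itself was the only gene that fell, with a log2 fold change of -3.06 ± 0.14 and an adjusted p of 2.07e-06. Genes of fat oxidation and fat storage had mostly positive values that did not pass over all genes. In the fatty acid oxidation list, 20 of 21 members were positive with a median of 0.33, and 1 rose adjusted over the list alone; examples are the long-chain acyl-CoA dehydrogenase Acadl with 0.56 ± 0.14 and the carnitine carrier Slc25a20 with 0.57 ± 0.23. In triglyceride synthesis, 14 of 15 members were positive with a median of 0.29, among them the phosphatidate phosphatase Lpin1 with 0.75 ± 0.21. Among circadian clock genes the median was 0.28, with 1 of 18 members that rose adjusted over the list alone, and the clock repressors Nr1d2 and Per3 had 0.55 ± 0.15 and 0.69 ± 0.21. These lists had adjusted p = 0.648, 0.648 and 0.636 with an estimated correlation. Their medians were 0.51, 0.48 and 0.44 without WT replicate 2, while that of fatty acid oxidation was 0.20 without WT replicate 3 and that of the clock genes 0.17 without WT replicate 1. Among DNA methylation and demethylation factors, 1 of 24 fell adjusted over the list alone; the list's smallest p was that of the methylcytosine dioxygenase Tet1, with -0.74 ± 0.14 and an adjusted p of 0.291 over all genes.

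T cell transcripts leaned the other way in Ing1-KO. All 17 T cell markers were negative with a median of -0.32, for example Cd8a with -0.63 ± 0.31 and Cd3e with -0.46 ± 0.24, and none passed over all genes or adjusted over the list alone. The list had an adjusted p of 0.0059, and adjusted p = 0.705 with an estimated correlation, and its call was lost at medians of -0.21 without WT replicate 3 and -0.14 without Ing1-KO replicate 1, and at -0.26 with normexp background correction. Macrophage, B cell and neutrophil and mast cell markers did not pass, with adjusted p of 0.403, 0.227 and 0.191. Their medians were negative as well, at -0.18, -0.21 and -0.24 with the array row as a block. Interferon-stimulated genes had a positive median of 0.16 with an adjusted p of 0.00427, and adjusted p = 0.705 with an estimated correlation. Their median was 0.10 and 0.37 without Ing1-KO replicates 2 and 3, and the call was lost at 0.04 without WT replicate 2 and at -0.00 without Ing1-KO replicate 1. Skeletal muscle transcripts were high in Ing1-KO replicate 1, where the list's mean deviation was 3.66, against -0.87 and -0.90 in replicates 2 and 3, and the list's median of 1.46 became -0.07 without that array, 2.27 without Ing1-KO replicate 2 and 0.79 with normexp. Limma called 1 gene of 31455, with 2716 at an unadjusted p under 0.05, and the groups did not overlap for 17.5% of genes, where chance gives 10%. Without WT replicate 2, WT replicate 3, Gadd45a-KO replicate 3 or DKO replicate 2 the count was 3, 2, 2 and 16, and the lists past the threshold fell from 16 to 6 without WT replicate 3.

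The double knockout against WT asks what loss of both genes does. The largest rises past the threshold were in the synaptic adhesion gene Slitrk4, 2.94-fold, the sperm acrosome gene Spaca1, 2.73-fold, the small GTPase gene Rasd1, 2.44-fold, and G0s2, an inhibitor of the triglyceride lipase Pnpla2, which rose 2.42-fold with a log2 fold change of 1.28 ± 0.18 (SE, n = 3 arrays per group). Further rises were in the acyl-CoA thioesterase Acot4 with 1.25 ± 0.18, the glycogen-targeting subunit Ppp1r3c with 1.22 ± 0.20, the choline dehydrogenase Chdh with 0.99 ± 0.16, Acadl with 0.98 ± 0.14 and the hexokinase Hk2 with 0.95 ± 0.16. The Gadd45a probe had 1.10 ± 0.13 in the arrays labelled DKO, with an adjusted p of 0.0287. That call was lost without WT replicate 1 or 3, Gadd45a-KO replicate 1 or 2, Ing1-KO replicate 2 or 3, or DKO replicate 1 or 2, where the value lay between 1.01 and 1.10. Ing1 fell by 3.14 on the log2 scale. The other largest falls were in the adhesion receptor gene Adgrb2 with -1.30 ± 0.21, the myeloid receptor genes Cd300c2 with -1.12 ± 0.17 and Lilra6 with -1.08 ± 0.18, Cstad with -1.10 ± 0.13, Begain with -0.97 ± 0.16, the fractalkine receptor Cx3cr1 with -0.95 ± 0.15, Tet1 with -0.91 ± 0.14, the glycosyltransferase B4galnt2 with -0.89 ± 0.15 and the adaptor Dok1 with -0.78 ± 0.13. Their adjusted p, Ing1 aside, lay between 0.0238 and 0.0441. Hk2 and Dok1 lie within 20 Mb of Gadd45a. Except for the Gadd45a probe, the mean of each gene named here lay on the same side of WT in Ing1-KO as in DKO. In WT, Ing1-KO and DKO the mean normalized log2 signal was 5.92, 7.46 and 7.47 for Slitrk4 and 7.92, 9.36 and 9.37 for Spaca1. For G0s2 it was 12.10, 12.69 and 13.37. So this comparison does not show that these changes need the loss of both genes.

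Oxidative fat metabolism stood out among the lists in DKO against WT. Of 21 fatty acid oxidation genes 1, Acadl, rose over all genes, and 20 rose and 1 fell adjusted over the list alone; the median was 0.73, with the medium-chain acyl-CoA dehydrogenase Acadm at 0.95 ± 0.19 and Slc25a20 at 1.06 ± 0.23. Of 27 oxidative phosphorylation genes, 17 rose adjusted over the list alone and 0 over all genes, with a median of 0.52 and the succinate dehydrogenase subunit Sdha at 0.62 ± 0.14. Of 20 brown and beige adipocyte markers, 12 rose and 1 fell adjusted over the list alone, with a median of 1.08; the lipid droplet protein gene Plin5 had 1.42 ± 0.32 and the nuclear receptor gene Ppara 1.21 ± 0.28. Of 24 white adipocyte markers, 9 rose adjusted over the list alone, with a median of 0.50 and the leptin gene Lep at 1.00 ± 0.24. Each of these 4 lists had adjusted p = 0.319 with an estimated correlation.

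C/EBP transcription factors and their textbook target genes leaned upward in the same fit of DKO against WT. Of 7 C/EBP transcription factors, 0 passed over all genes and 2 rose adjusted over the list alone, with a median of 0.44, the bZIP partner gene Cebpg at 0.55 ± 0.10, and adjusted p = 0.319 with an estimated correlation. Of 26 textbook C/EBP target genes, 10 rose adjusted over the list alone and 0 over all genes, with a median of 0.38 and adjusted p = 0.352 with an estimated correlation. Of 21 senescence genes, 3 fell adjusted over the list alone and 0 over all genes, with a median of -0.39 and adjusted p = 0.319 with an estimated correlation. The p53 target genes did not pass, with a median of 0.01 and an adjusted p of 0.627. The median of the transcription factors was 0.26 without WT replicate 3, and that of the target genes 0.19 without WT replicate 3 and 0.58 without WT replicate 2 or DKO replicate 3. The senescence call was lost without WT replicate 1, at -0.25, and without DKO replicate 3, at -0.47. It was also lost with normexp, at -0.36, and the median was -0.26 with the authors' values.

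T cell and proliferation genes moved the other way in DKO against WT. Of 17 T cell markers, 15 fell adjusted over the list alone and 0 over all genes, with a median of -0.84 and examples such as Cd3e with -0.93 ± 0.24 and Cd8a with -1.08 ± 0.31. Of 25 proliferation genes, 10 fell adjusted over the list alone, with a median of -0.61, among them the anaphase genes Ube2c with -0.71 ± 0.18 and Cdc20 with -0.83 ± 0.22. With an estimated correlation, these lists had adjusted p = 0.319 and adjusted p = 0.397, and without DKO replicate 2 their medians were -0.48 and -0.39. The T cell list's mean deviation was -0.50, -1.29 and 0.01 in the 3 DKO arrays, while the fatty acid oxidation list had 0.65, 0.53 and 0.34 in the same arrays. Skeletal muscle transcripts were high in DKO replicate 1, with a mean deviation of 2.26; without the 3 arrays highest in them, a setting chosen after the data were seen, the medians were 0.66 for fatty acid oxidation, 0.92 for brown and beige markers and -0.91 for T cell markers.

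Limma called 52 of 31455 genes in DKO against WT, 26 higher and 26 lower, of which 29 changed at least 2-fold and 33 carry a name. In all, 7230 had an unadjusted p under 0.05, and the groups did not overlap for 22.3% of genes, where chance gives 10%. With the slide, which is the replicate number, as a block the count was 654. Within the 3 slides the median of the fatty acid oxidation list was 0.93, 0.43 and 0.85 and that of the T cell list -0.69, -1.33 and -0.52. With centring on the median in place of the 75th percentile 71.4% of 63 calls were higher, against 50% of the 52. The count rests on single arrays, since it was 1, 1127 and 2 without WT replicates 1, 2 and 3, 1, 1 and 233 without Gadd45a-KO replicates 1, 2 and 3, 32, 2 and 2 without Ing1-KO replicates 1, 2 and 3, and 2, 1 and 3332 without DKO replicates 1, 2 and 3. In these fits the median signed log2 fold change of the 52 genes lay between 0.99 and 1.14, against 1.09, and their median SE between 0.16 and 0.19, against 0.16. The count was 200 with normexp background correction, 24 with no filter, 4 with plain eBayes, 3 with the array row and 1 with the array column as a block, 1 with only the arrays of these groups, and 1 without the arrays highest in muscle transcripts.

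DKO against Gadd45a-KO asks what loss of Ing1 does where Gadd45a is missing too, and gave the broadest difference. With the Gadd45a labels turned round, which stays open, it would be loss of Ing1 where Gadd45a is present. The thermogenic uncoupling protein gene Ucp1 rose 6.03-fold, with a log2 fold change of 2.59 ± 0.78 (SE, n = 3 arrays per group) and a mean normalized log2 signal of 14.78 ± 0.83 in DKO against 12.19 ± 1.74 in Gadd45a-KO (SD). The potassium channel gene Kcnk2 rose by 2.40 ± 0.47, imprecise since it was above background on 2 of 3 Gadd45a-KO arrays, Lrmda by 2.35 ± 0.69 and the carboxypeptidase N subunit gene Cpn2 by 2.15 ± 0.53. The epidermal envelope gene Lce1e, below background in Gadd45a-KO, was at least 3.91-fold higher. This too is imprecise, since it was above background on 2 of 3 DKO arrays. The largest falls were in neutrophil granule genes. Ngp was at least 14.4-fold lower and below background in all 3 DKO arrays, Ltf fell to a signal near background, above it on 2 of 3 DKO arrays, so that its value of -4.58 ± 1.28 is imprecise, Camp changed by -3.99 ± 0.63 and S100a9 by -3.65 ± 0.78, and the vomeronasal receptor gene Vmn1r197 was at least 3.69-fold lower. Ing1 fell by 3.23 on the log2 scale, and the Gadd45a probe was 0.44 ± 0.13 higher in the arrays labelled DKO, with an adjusted p of 0.0456, a call kept with 1 array left out only without WT replicate 1 or 2, where the value was 0.44, and lost without each of the 10 others, where it lay between 0.38 and 0.49.

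Genes of fat oxidation and of the fat cell rose together in DKO against Gadd45a-KO. Of 21 fatty acid oxidation genes 19 rose and 1 fell, 20 and 1 adjusted over the list alone, with a median of 0.94; Acadl had 1.13 ± 0.14, the hydroxyacyl-CoA dehydrogenase Hadh 1.04 ± 0.16 and Acadm 1.09 ± 0.19. Of 27 oxidative phosphorylation genes 17 rose and 0 fell, 25 and 0 adjusted over the list alone, with a median of 0.70 and Sdha at 0.72 ± 0.14. Of 20 brown and beige markers 8 rose and 1 fell, 16 and 1 adjusted over the list alone, with a median of 1.13; the coactivator Ppargc1a had 1.17 ± 0.26, and the beige marker Tmem26 fell, with -1.48 ± 0.24. White adipocyte markers rose in 14 of 24 cases, 22 adjusted over the list alone, with a median of 0.82, including Lep with 1.34 ± 0.24 and the fatty acid transporter Cd36 with 0.97 ± 0.18. Triglyceride synthesis genes rose in 7 of 15 cases, 12 adjusted over the list alone, including Lpin1 with 1.25 ± 0.21, and lipolysis genes in 5 of 18, 14 adjusted over the list alone, including G0s2 with 1.54 ± 0.18. Cholesterol synthesis genes rose in 8 of 19 cases, 12 adjusted over the list alone, among them the synthase gene Hmgcs1 with 1.16 ± 0.21. All 7 lists passed camera, and each had adjusted p = 0.286 with an estimated correlation.

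C/EBP transcription factors rose in 3 of 7 cases, 4 rose and 2 fell adjusted over the list alone, with Cebpa at 0.78 ± 0.22 and Cebpg at 0.67 ± 0.10. The list did not pass, with an adjusted p of 0.132. Of 26 textbook C/EBP target genes 9 rose and 3 fell, 15 and 4 adjusted over the list alone, with a median of 0.62 and adjusted p = 0.308 with an estimated correlation; the acute phase gene Saa3 fell, with -2.67 ± 0.58. Of 23 p53 target genes 2 rose and 2 fell, 2 and 4 adjusted over the list alone, with a median of 0.04 and an adjusted p of 0.919, and the apoptosis gene Pmaip1 fell with -1.36 ± 0.23. Of 21 insulin signalling and glucose uptake genes 7 rose and 1 fell, 9 and 2 adjusted over the list alone, with Hk2 at 1.05 ± 0.16, and adjusted p = 0.286 with an estimated correlation. Its median of 0.40 was 0.26 with the array column as a block.

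Immune, senescence and proliferation genes fell in the same comparison. Of 17 T cell markers 15 fell, 17 adjusted over the list alone, with a median of -1.08, including Gata3 with -0.93 ± 0.16 and Cd3e with -1.01 ± 0.24. Of 19 macrophage markers 6 fell, 7 adjusted over the list alone, with the growth factor receptor Csf1r at -0.83 ± 0.12, and of 17 B cell markers 6 fell, 16 adjusted over the list alone, with a median of -0.80. Neutrophil and mast cell markers fell in 6 of 15 cases, 9 adjusted over the list alone, with a median of -1.66. In the senescence list 8 of 21 genes fell, 9 adjusted over the list alone, led by the chemokine Ccl8 with -2.83 ± 0.29, the cytokine Il1b with -1.67 ± 0.26 and the cell cycle inhibitor Cdkn2a with -1.60 ± 0.30. Of 25 proliferation genes 17 fell, 21 adjusted over the list alone, with a median of -0.88 and Cdc20 at -1.13 ± 0.22. DNA methylation and demethylation factors fell in 8 of 24 cases, 9 fell and 1 rose adjusted over the list alone, including Tet1 with -0.73 ± 0.14, Gadd45b with -0.98 ± 0.19 and Uhrf1 with -0.90 ± 0.21. With an estimated correlation, the T cell, neutrophil and mast cell, senescence and DNA methylation lists had adjusted p = 0.286, and the macrophage, B cell and proliferation lists adjusted p = 0.291. Endothelial markers, which are also not fat cell genes, had a median of 0.43, with 1 of 17 that rose both over all genes and adjusted over the list alone, Tek at 0.97 ± 0.24, and adjusted p = 0.384 with an estimated correlation; red blood cell transcripts rose in 5 of 9 cases, 8 adjusted over the list alone, with adjusted p = 0.286 with an estimated correlation. Without DKO replicate 2 the median was -0.47 for B cell markers and 0.21 for endothelial markers. The DNA methylation call was lost without WT replicate 2, Gadd45a-KO replicate 1, Gadd45a-KO replicate 3 and DKO replicate 3, at medians of -0.15, -0.17, -0.12 and -0.10, with median centring, at -0.08, and with the filter on all 12 arrays, at -0.11. The neutrophil and mast cell median was -0.71 with normexp, -0.60 with the filter on all 12 arrays, -1.04 with the authors' values and -0.90 without the 3 arrays highest in muscle transcripts.

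Limma called 4720 of 31455 genes in DKO against Gadd45a-KO, 2043 higher and 2677 lower, of which 1287 changed at least 2-fold, 361 up and 926 down. In all, 10369 had an unadjusted p under 0.05, and the groups did not overlap for 37.3% of genes, where chance gives 10%. With the slide as a block the count was 6099. Within the 3 slides the median of the fatty acid oxidation list was 0.84, 0.92 and 1.03 and that of the T cell list -0.85, -1.71 and -0.66. With centring on the median 58.9% of 4238 calls were higher, against 43.3%. The count was 3058 without Ing1-KO replicate 3, 1086 and 545 without Gadd45a-KO replicates 2 and 3, and 889 and 648 without DKO replicates 1 and 2. It was 3078 with no filter, 500 with only the arrays of these groups, 3 with the array column as a block and 1 without the 3 arrays highest in muscle transcripts. In the last of these the median signed log2 fold change of the 4720 genes was 0.81, against 0.78, and their median SE 0.24, against 0.19.

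**Figure D2:**
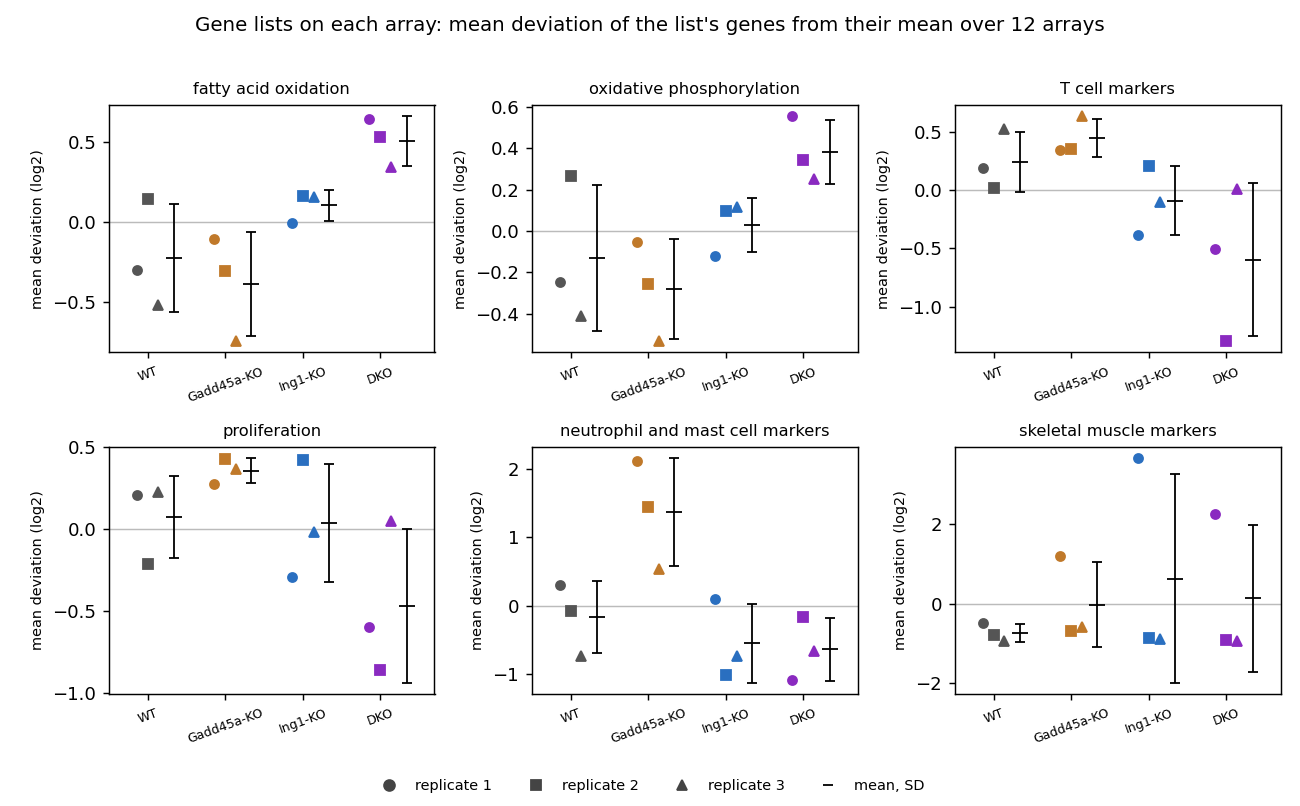
Mean deviation of 6 gene lists (y axis, log2, from each gene's mean over 12 arrays) on each array, by genotype (x axis), with symbols for the replicate number and the mean with its SD beside them. Fatty acid oxidation lies between 0.34 and 0.65 in DKO and between -0.75 and -0.11 in Gadd45a-KO, and skeletal muscle transcripts are high in replicate 1 of Ing1-KO, with 3.66, and of DKO, with 2.26.

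DKO against Ing1-KO asks what loss of Gadd45a does where Ing1 is missing too. The 1 gene that passed was Gadd45a itself, whose probe was 2.66-fold higher in the arrays labelled DKO, with a log2 fold change of 1.41 ± 0.13 (SE, n = 3 arrays per group) and an adjusted p of 0.00603. Ing1 did not differ detectably, with -0.08 ± 0.14. Fat oxidation genes had a positive lean in DKO. Of the lists, 20 of 21 fatty acid oxidation genes and all 27 oxidative phosphorylation genes were positive, with medians of 0.42 and 0.35. So were 19 of 20 brown and beige markers, with a median of 0.61. Acadl had 0.42 ± 0.14 and Hadh 0.45 ± 0.16, and the fatty acid binding protein gene Fabp3 had 1.95 ± 0.80. Proliferation genes had a median of -0.49, T cell markers of -0.50 and interferon-stimulated genes of -0.43, with the antiviral synthetase Oas2 at -0.86 ± 0.32. No member of these 6 lists passed, over all genes or adjusted over the list alone, and each list had adjusted p = 0.353 with an estimated correlation. Without DKO replicate 2 the proliferation and T cell medians were -0.26 and -0.14, and without DKO replicate 3 -0.80 and -0.81. Without the 3 arrays highest in muscle transcripts the median was 0.35 for brown and beige markers, 0.21 for oxidative phosphorylation and -0.23 for interferon-stimulated genes. Limma called 1 of 31455 genes in this comparison, with 1104 at an unadjusted p under 0.05, and the groups did not overlap for 8.92% of genes, where chance gives 10%. Gadd45a no longer passed, and the count was 0, without Ing1-KO replicate 2, Ing1-KO replicate 3 or DKO replicate 2, with the array column or slide and row as blocks, with only the arrays of these groups and without the arrays highest in muscle transcripts. The count was 3 without DKO replicate 1 and 2 without DKO replicate 3.

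The interaction asks whether the loss of Ing1 acts differently with and without Gadd45a. With the Gadd45a labels turned round every sign of it would turn. No gene passed. The smallest p belonged to Ccl12 with an interaction of -1.42 ± 0.21 on the log2 scale, Pdgfrl with 1.94 ± 0.36, the membrane skeleton gene Epb41l3 with -0.77 ± 0.14, Csmd1 with -1.59 ± 0.31 and Tspan10 with -1.61 ± 0.33, none of which pass, with adjusted p between 0.639 and 0.727. Limma called 0 of 31455 genes, with 1861 at an unadjusted p under 0.05. With genes simulated to change 2-fold in the interaction, 8.82% of 68 were recovered, and of those changed 4-fold 68.3% of 60, against 49.2% of 65 and 87.8% of 74 in DKO against Gadd45a-KO. So the larger count in one comparison does not show that the effect of Ing1 loss differs between the 2 backgrounds for any single gene. Each simulation changed 200 genes, so its shares need not hold in DKO against Gadd45a-KO as measured, where 4720 genes were called. Of 32 lists 20 passed camera for the interaction, and 0 with an estimated correlation, where the lowest adjusted p = 0.348.

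Across the 31455 genes, log2 fold changes for Ing1 loss with and without Gadd45a, which share no arrays, had a Pearson correlation of 0.50 and a Spearman correlation of 0.55, against -0.003 simulated for unchanged groups. Genes are not independent replicates, so this is a description. With no filter on dim probes the Pearson correlation was 0.31, and its SD over the 3 slides was 0.31. Those for Gadd45a loss with and without Ing1 had -0.30 and -0.41, with a Pearson correlation of -0.16 with no filter and -0.45 with the filter on all 12 arrays. Against the shared WT arrays, Ing1-KO and DKO had a correlation of 0.73 and a covariance of 0.117, where unchanged groups gave 0.50 and 0.0448. Gadd45a-KO and DKO had -0.04 and -0.0057, where unchanged groups gave 0.50 and 0.0450, and Gadd45a-KO and Ing1-KO had 0.21 and 0.0213, where they gave 0.50 and 0.0450. With no filter these 2 correlations were 0.16 and 0.35, and with the filter on all 12 arrays -0.24 and 0.05. Of the 52 genes called between DKO and WT, 25 higher and 26 lower ones were also called in the same direction between DKO and Gadd45a-KO, where independent lists would share 1.69 and 2.21 and unchanged groups shared 0. Neither number says what to find without a shared effect, because the unchanged groups leave out the effects and the independent lists leave out the DKO arrays that both comparisons share.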

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

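The tests of array row, array column, cell types, scaling, labels and linked DNA in this part were chosen after the results were seen; the counts over other splits of the arrays were fixed before.

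The effect of Ing1 loss differed between the 2 Gadd45a backgrounds, by camera on the interaction at the preset correlation, for 20 of 32 gene lists, each of them lost with adjusted p = 0.348 or higher with an estimated correlation. The median interaction, on the log2 scale, was 0.51 for white adipocyte markers, 0.67 for de novo lipogenesis, 0.45 for triglyceride synthesis, 0.36 for lipolysis and its control, 0.64 for brown and beige adipocyte markers, 0.59 for fatty acid oxidation and 0.50 for oxidative phosphorylation. It was 0.25 for insulin signalling and glucose uptake, 0.44 for textbook C/EBP target genes, 0.53 for cholesterol synthesis and uptake, 0.29 for endothelial markers and 0.43 for red blood cell transcripts. It was -0.54 for senescence and its secretome, -0.81 for proliferation, -0.34 for macrophage markers, -0.71 for T cell markers, -0.61 for B cell markers, -1.45 for neutrophil and mast cell markers, -0.54 for interferon-stimulated genes and -1.11 for skeletal muscle markers. Many of these rest on single arrays, most of all on WT replicate 2, which was also the dimmest array. Without it the median was 0.33 for white adipocyte markers, 0.40 for lipogenesis, 0.20 for triglyceride synthesis and 0.19 for lipolysis. It was 0.39 for fatty acid oxidation, 0.29 for oxidative phosphorylation and -0.28 for interferon-stimulated genes. The calls of C/EBP targets, at 0.25, and endothelial markers, at 0.12, were lost without that array.

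Other arrays left out moved these medians by over 1.5 times or ended a call. Without WT replicate 1 macrophage markers had -0.61, and the insulin call was lost at 0.16, and without WT replicate 3 macrophage markers had -0.21. Without Gadd45a-KO replicate 1 the skeletal muscle call was lost at -0.67, and without replicate 2 interferon-stimulated genes had -0.32. Without Gadd45a-KO replicate 3 lipogenesis had 0.40 and triglyceride synthesis 0.28, and the calls of endothelial markers, insulin signalling and red blood cells were lost at 0.26, 0.26 and 0.23. Without Ing1-KO replicate 1 skeletal muscle turned to 0.22, interferon-stimulated genes had -0.29 and insulin signalling 0.39, and the insulin call was lost without Ing1-KO replicates 2 and 3, at 0.18 and 0.16. Without DKO replicate 1 skeletal muscle had -1.87, and the calls of insulin signalling and C/EBP targets were lost at 0.19 and 0.32. Without DKO replicate 2 T cell, B cell, interferon and red blood cell lists had -0.32, -0.25, -0.34 and 0.24, and the calls of endothelial markers, insulin signalling and skeletal muscle were lost at 0.06, 0.18 and -0.62. Without DKO replicate 3 macrophage markers had -0.21 and insulin signalling 0.41, and the skeletal muscle call was lost at -0.72.

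Other alternatives moved these medians too, and the signs of all of them would turn with the Gadd45a labels turned round. With the array column as a block the calls of insulin signalling, C/EBP targets, endothelial markers and red blood cells were lost at 0.10, 0.32, 0.16 and 0.31, skeletal muscle had -2.31 and triglyceride synthesis 0.30. With normexp background correction the calls of triglyceride synthesis, insulin signalling, C/EBP targets and endothelial markers were lost at 0.37, 0.15, 0.37 and 0.23, and macrophage, neutrophil and mast cell, senescence and skeletal muscle lists had -0.22, -0.33, -0.25 and -0.63. The insulin call was also lost with quantile normalization, at 0.20, with the authors' values, at 0.14, and with no filter or the filter on all 12 arrays, at 0.25. Endothelial markers had 0.18 with the authors' values, and neutrophil and mast cell markers -0.90 with no filter and -0.30 with the filter on all 12 arrays. Without the 3 arrays highest in muscle transcripts the calls of neutrophil and mast cell and of skeletal muscle markers were lost at -0.08 and -0.29, while interferon-stimulated genes had -0.26, endothelial markers 0.55, insulin signalling 0.38 and red blood cells 0.66.

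Between DKO and Gadd45a-KO 4720 genes were called, with fat oxidation genes higher and immune genes lower in DKO. The array row is argued against as a cause, since with it as a term of the fit 3340 genes were called and 3148 of the 4720 stayed called. A higher share of all cells other than fat cells in the Gadd45a-KO pools stays open. T cell markers were 1.04 lower in DKO and endothelial markers 0.41 higher, with a difference of -1.45 ± 0.62 (SE). Both lists were picked with their directions in this comparison known, so their moving apart cannot decide it. A change in immune cells alone stays open too. For single genes the array column stays open. With it as a term 3 genes were called, while the median SE of the 4720 genes went from 0.19 to 0.23. Their median signed log2 fold change went from 0.78 to 0.73. These genes and signs were picked in this comparison, so that median does not decide. For the gene lists, fixed before the data were examined, the column is argued against as the cause of their shifts. With it 29 of 32 lists kept their call and direction. The medians were then 1.07 for fatty acid oxidation and -0.96 for T cell markers. Of the other lists 1 lost its call, 1 gained one and 1 turned round. The genotype itself stays open as a biological explanation.

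The Gadd45a probe was higher in arrays labelled as lacking Gadd45a. Scaling between arrays is argued against, since 4 other scalings gave a log2 fold change between DKO and Ing1-KO of 1.30 to 1.43, with an adjusted p of 0.0222 at most. Gadd45a labels turned round in all 12 arrays cannot be told apart from correct labels: the lowest signal in arrays labelled as having the gene, 9.06, lies far above the background limit of 4.75, but this decides only if the probe lies in the deleted part, which the files do not say. A transcript that the targeted allele still makes may be measured by this probe, and this was not tested.

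Genes near the targeted loci were frequent among the smallest p between DKO and Ing1-KO, genes named here after their values were seen. Of 162 genes near Ing1 7 had an unadjusted p under 0.01 (odds ratio 13.4, Fisher's exact p = 2.41e-06, adjusted p = 2.89e-05), such as Tti2 with 0.84 and Csmd1 with -0.86, and of 227 near Gadd45a 7 did (odds ratio 9.58, exact p = 1.96e-05, adjusted p = 0.000118), such as Cd207 with 1.13 and Herc6 with -1.06. For linked DNA of another strain around Ing1, 1 of 70 stretches of 40 Mb elsewhere held as high a share in Ing1-KO against WT and 57 of 70 in DKO against Gadd45a-KO. These 2 comparisons do not address the pattern, since DKO and Ing1-KO both lack Ing1, and a linked stretch of the same length in both would not differ between them. Only stretches of different length in the 2 genotypes could. In DKO against Ing1-KO, the pattern itself, 0 of 70 stretches held as high a share. The genes near Ing1 at that p in both Ing1-KO against WT and DKO against Ing1-KO turned sign between them. Tti2 had -0.70 and 0.84, and Gm15056 had 1.70 and -2.44. Both comparisons share the Ing1-KO arrays, which alone can turn signs, so this does not decide it. For linked DNA of another strain around Gadd45a, 1 of 69 stretches held as high a share in DKO against Ing1-KO, which is the pattern itself, and 18 of 69 in Gadd45a-KO against WT. That 1 stretch overlaps the one around Ing1. With stretches around Ing1 left out, the highest share elsewhere in DKO against Ing1-KO was 2.13%, against 3.08% near Gadd45a. Near Gadd45a, Cd207 was at that p with the same sign in both, with 1.13 in DKO against Ing1-KO and 1.74 in Gadd45a-KO against WT. These 2 comparisons share no array, but 1 gene named after its values were seen does not decide. Linked DNA around Gadd45a stays open too, and no file holds genotypes of the flanking DNA.

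With 10 splits of 6 arrays the splits are too few for a share under 0.05. Of the 10 splits, the real one included, 10 gave as many genes as Gadd45a-KO against WT, with 0 called and 0 in the highest other, which a count of 0 makes certain. For Ing1-KO against WT 2 did, with 1 called and 1 in the highest other, and for DKO against Gadd45a-KO 1 did, with 4720 called and 0 in the highest other. For DKO against WT 2 did, with 52 called and 2912 in the highest other, which sets WT replicates 1 and 3 with DKO replicate 3 against the rest and points to a structure of the samples. For DKO against Ing1-KO 2 did, with 1 called and 227 in the highest other, Ing1-KO replicate 1 with DKO replicates 1 and 2 against the rest. For the interaction 0 genes were called, so that all 100 of 100 drawn splits had to give as many, with 46 in the highest other, and this test decides nothing.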

How the results depend on the processing

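The alternatives named here were fixed before the results were seen, except the fit without the 3 arrays highest in skeletal muscle transcripts, the fit with slide and array row, the fit without 2 arrays, the odds ratio at an unadjusted p under 0.01 and the fold changes of Ing1 and Gadd45a with only the arrays compared, which were added after. The fit without WT replicate 2 and DKO replicate 3 was picked after the counts with 1 array left out were seen, because these 2 gave the highest counts, and it is not interpreted. The fall of Ing1 kept its call in every alternative run, and the interaction had 0 genes in each. Where a value moved, the cause was not tested.

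The counts stand in the order Gadd45a-KO, Ing1-KO and DKO against WT, then DKO against Gadd45a-KO and DKO against Ing1-KO. In the analysis as planned they were 0, 1, 52, 4720 and 1. The genes called in the same direction, DKO vs WT and DKO vs Gadd45a-KO, were 51. In the Ing1-KO against WT comparison the count was 5 with quantile normalization, 4 with median centring, 2 with normexp, 2 with the authors' values, 8 with every probe tested and 2 without the 2 arrays. In DKO against WT it was 200 with normexp, 24 with no filter, 4 with plain eBayes, 1 with only the arrays compared, 654 with the replicate number as a block, 3 with the row, 1 with the column, 1 without the muscle-high arrays, 2 with slide and row, and 6849 without the 2 arrays. The genes called in both comparisons were, in the same order, 195, 23, 4, 1, 642, 3, 1, 1, 2 and 6140. In DKO against Gadd45a-KO the count was 3078 with no filter, 500 with only the arrays compared, 3 with the column, 1 without the muscle-high arrays and 9216 without the 2 arrays. In DKO against Ing1-KO it was 0 with only the arrays compared, 0 with the column, 0 without the muscle-high arrays, 0 with slide and row and 5 without the 2 arrays. With 1 array left out the counts ranged from 0 to 1, 1 to 16, 1 to 3332, 545 to 7073 and 0 to 3, and the genes called in both from 1 to 3189.

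The lists past the threshold, 16, 16, 20, 22, 17 and 20 with the interaction last, were 0 in each of the 6 with an estimated correlation. They were 11 in DKO against Ing1-KO with the column as a block and 7 in Gadd45a-KO against WT without the 2 arrays. With 1 array left out they ranged from 4 to 19 in Gadd45a-KO against WT and from 6 to 21 in Ing1-KO against WT.

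The Gadd45a log2 fold change in DKO against Gadd45a-KO no longer passed at 0.42 with normexp, 0.42 with the authors' values, 0.44 with no filter, 0.44 with plain eBayes, 0.44 with only the arrays compared, 0.42 with the row, 0.47 with the column, 0.49 without the muscle-high arrays and 0.43 with slide and row, and ranged from 0.38 to 0.49 with 1 array left out, passing only without WT replicate 1 or 2. In DKO against Ing1-KO it no longer passed at 1.41 with only the arrays compared, 1.30 with the column, 1.46 without the muscle-high arrays and 1.41 with slide and row, and ranged from 1.34 to 1.46 with 1 array left out, lost without Ing1-KO replicate 2 or 3 or DKO replicate 2. In DKO against WT it no longer passed at 1.10 with plain eBayes, 1.10 with only the arrays compared, 1.10 with the row, 1.09 with the column, 1.10 without the muscle-high arrays and 1.10 with slide and row, and ranged from 1.01 to 1.24 with 1 array left out, passing only without WT replicate 2, Gadd45a-KO replicate 3, Ing1-KO replicate 1 or DKO replicate 3. The correlation of Gadd45a-KO and DKO against shared WT turned to 0.16 with no filter and was -0.24 with the filter on all 12 arrays, and that of Gadd45a loss with and without Ing1 was -0.45 with that filter and -0.16 with no filter. By less than the SD over slides, that of Ing1 loss with and without Gadd45a moved to 0.31 with no filter, and that of Gadd45a-KO and Ing1-KO to 0.35 with no filter and 0.05 with the filter on all 12 arrays. The odds ratio near Gadd45a in DKO against WT was 1.68 (Fisher's exact p = 0.00539) with genes at an unadjusted p under 0.01, against 4.65 (exact p = 0.0757) with called genes.

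List medians that changed direction with 1 array left out ranged, in Gadd45a-KO against WT, from -0.32 without WT replicate 3 to 0.0326 without WT replicate 2 for fatty acid oxidation, for which camera's direction turned at a median of -0.0192 without Gadd45a-KO replicate 3, and from -0.30 to 0.0635 without the same arrays for oxidative phosphorylation. Without both WT replicate 2 and DKO replicate 3 these were 0.0326 and 0.0635 too. Skeletal muscle markers ranged from -0.0704 without Ing1-KO replicate 1 to 2.27 without Ing1-KO replicate 2 in Ing1-KO against WT, from -1.46 without DKO replicate 1 to 0.91 without Ing1-KO replicate 1 in DKO against Ing1-KO, and from -1.87 to 0.22 without the same arrays in the interaction. Extracellular matrix genes in DKO against Ing1-KO ranged from -0.22 without DKO replicate 2 to 0.17 without Ing1-KO replicate 1. Without the muscle-high arrays skeletal muscle markers had -0.0704 in Ing1-KO against WT, and with the column as a block they had -1.14 in DKO against Gadd45a-KO. For 2 lists in DKO against Ing1-KO the median stayed positive and only camera's direction turned: immediate early genes had 0.24 without the muscle-high arrays, against 0.0635, and triglyceride synthesis had 0.0492 with the column as a block, against 0.20. Of 4794 list medians 4327 kept their call and direction, as did 19132 of 20343 fold changes of named genes, of which 0 turned round.

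The arrays share only a number by their names, which is also the slide. Of 18 pairs of same-numbered arrays of different genotype, 9 had a correlation over 0.1, from -0.28 to 0.42, with a median of 0.12 against -0.10 for pairs of different numbers, and 9 of 12 arrays correlated best with one of their own number.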

Other observations

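The clock, stress and tissue lists hold values not described above, and the arrays high in muscle transcripts were looked for after the results were seen. Heat shock and unfolded protein genes had a median of 0.19 in DKO against Gadd45a-KO, where 2 of 18 rose and 1 fell, 4 and 1 adjusted over the list alone, with the stress factor gene Ddit3 at 0.51 ± 0.11, and adjusted p = 0.286 with an estimated correlation. That call was lost without Gadd45a-KO replicate 2, DKO replicate 1 or DKO replicate 3, at medians of 0.17, 0.17 and 0.16. It was lost too with quantile normalization, the authors' values, the filter on all 12 arrays, and the array row and the array column as a block, at medians of 0.16, 0.17, 0.19, 0.15 and 0.18. Circadian clock genes had 0.22 there, with 2 of 18 that rose over all genes and also adjusted over the list alone, Clock at 0.71 ± 0.19 and Nfil3 at 0.65 ± 0.18, and adjusted p = 0.286 with an estimated correlation. Their median was 0.35 without DKO replicate 1, and the call was lost at 0.13 without DKO replicate 3 and at 0.22 with the filter on all 12 arrays. The median was 0.38 without the 3 arrays highest in muscle transcripts. Extracellular matrix genes had a median of 0.11 and did not pass, with an adjusted p of 0.369, with 2 of 26 that rose and 1 that fell, 1 and 0 adjusted over the list alone. There the crosslinking enzyme gene Lox rose with 1.18 ± 0.26 and the inhibitor Timp1 fell with -1.58 ± 0.47. Progenitor and fibroblast markers did not pass either, with a median of 0.14 and 0 of 19 members past the threshold. Epididymis markers, from the organ next to this fat depot, had 3 measured members and a median of 0.29, with an adjusted p of 0.396.

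Skeletal muscle transcripts were highest in Ing1-KO replicate 1, DKO replicate 1 and Gadd45a-KO replicate 1, with mean deviations of 3.66, 2.26 and 1.20, and lay at -0.48 in WT replicate 1, on the same slide. In the principal components of all arrays the first held 33.8% of the variance and the second 16.9%, and WT replicate 2 stood apart on the second, at -78.6.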
